A study of Gallus gallus with 6 samples.

How the data were processed

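Pituitary glands of chickens at embryonic day 17 (E17, 3 birds) and post-hatch day 3 (PH3, 3 birds) were compared on spotted cDNA arrays. Per the labels' protocols, each sample was the gland of 1 bird, so the replicates are separate animals. The labels place PH3 birds 2 days after hatching, which usually follows about 21 days of incubation. Total RNA (500 ng per sample) was amplified by the Eberwine procedure, in which oligo(dT)-primed cDNA carrying a T7 promoter is transcribed into antisense RNA. Amplified RNA of each bird (1 microgram) was labelled with Cy3, and every array was hybridized with 1 common Cy5-labelled reference made of 2 micrograms from each of the 6 samples. No array had the dyes swapped. The reference is the same on all arrays. It would cancel in a difference of log ratios between the stages, as would a dye bias that is an equal offset on every array. Whether this holds for the deposited values was not tested.

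The deposited table holds 1 value per spot and array for 7200 spots. The deposited values appear to have been rescaled within stretches of rows, and are read here as standardized scores and not as plain log2 ratios. Each of the 8 stretches of 900 consecutive rows has, on each array, a mean between -0.0214 and 0.0146 and a standard deviation between 1.008 and 1.023. Stretches of 450 rows do not show this, with standard deviations between 0.9404 and 1.094. A difference of 1 score unit is therefore about the spread of the spots of that array, and no fold change can be given. Scanner, background correction, normalization, standardization method and the orientation of the score (sample over reference or the inverse) are not given in the sources used here. The titles name each sample first, vs the reference pool, but do not say how the value was formed or from which quantity. Scores correlated at 0.771 to 0.902 across probes between stages, and mean scores over probes had an SD of 0.954. Much of a score was therefore shared by all arrays. This leaves open whether the value is a ratio to the pool at all, which was not tested. Spot intensities were not used here, so the signal over background of a spot is unknown, and the number of arrays limits the precision. The planned test assumed log2 ratios, and the same linear model was applied to the scores as deposited. The planned threshold of a 1.5-fold change could not be applied to scores.

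Gene names were sought in the platform annotation. It lists 54 of the 7200 probes, all with 1 symbol (STUB1) and 1 accession, none with several symbols, and 7146 probes are unnamed here. The 54 probes did not behave as copies of 1 sequence (values in the Results), so no probe is reported under a gene name. The planned gene-level test and the lists of pituitary hormones, transcription factors, releasing-hormone receptors, cell cycle genes and markers of other cell types could not be applied. The planned rule for named genes allows, where probes are unnamed, at most 2 probe numbers in each direction. Called probes whose 3 scores of one stage all lie above the 3 of the other are ordered by the size of the difference, and where fewer than 5 are called in a direction, those with the smallest unadjusted p are given as not passing.

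Probes with at least 2 values in each stage (7145 of 7200) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, stage as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 residual degrees of freedom were supplemented by 3.36 prior degrees of freedom. The median half-width of the 95% interval of a difference was 0.442 score units. The test was checked on simulated data for 7145 probes with 50 changed probes of each size and a spread between probes as estimated from these arrays. In 20 runs it recovered 2.3% of differences of 0.5, 46.1% of differences of 1, 92.1% of differences of 2 and 97.6% of differences of 3 score units. Of its calls, 5.4% were false. The changed probes were drawn at random and had independent noise. In the data, the 32 probes that differed by more than 2 units had a median within-stage SD of 0.894, against 0.232 for all probes. The test called 4 of them, so the simulated rates need not hold for the large differences seen here. All sizes were also planted in the same runs, where many calls ease the Benjamini-Hochberg adjustment for each probe. With 4 calls in the data, the simulated rates need not hold at any size.

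The orientation of the scores was tested from the make-up of the reference. As it holds equal shares of the 6 samples, an unbiased linear ratio of sample to reference would average 1 for each probe, which would bend the mean log ratio downwards as the stage difference grows. The inverse ratio would bend upwards. The deposited scores do not meet this premise probe by probe, since many lie far from 0 with little stage difference. The slope can be read only if these offsets are unrelated to the size of the stage difference. In spread they were not. The SD of mean scores was 0.845 for differences under 0.25 units and 1.69 for those over 2. Whether their average also depends on the difference was not tested. The slope of the mean of the 2 stage means on this curve was fitted over probes after centring each array on its median. It first used the plain mean over arrays, which weights the stages unequally when 1 array is left out, and was changed after that result was seen. The first form gave slopes between -1.982 and -0.2391 with 1 array left out, and -0.4932 without PH3 replicate 2. In simulated data the slope was -1.022 ± 0.265 (SD over 20 runs) for sample over reference and 0.9576 ± 0.243 for the inverse, where the scores were log2 ratios.

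The main test has no term for the replicate number. The test, the threshold, the rule for named genes and the following alternatives were set before the data were examined: median centring, quantile normalization, scaling to equal spread, complete probes, robust moderation, array weights, the replicate number as a block, other thresholds, an unmoderated model and leaving out each array. Alternatives added after the data were seen set each stretch again to mean 0 and standard deviation 1, or left out probes with 1 array standing apart by more than 3 units, in 2 forms. The first form measured the distance from the median of the other 5 arrays. It was replaced, after its result was seen, by the distance beyond all of the other 5. All columns of values in the table belong to the 6 samples.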

Results

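The study compared the chicken pituitary gland before and after hatching, at E17 and at PH3, with 3 birds per stage. The pituitary is the endocrine gland below the brain that secretes hormones controlling growth, metabolism, stress responses and reproduction. Each bird's amplified RNA was set against the same reference pool on 1 array, and the value of a spot is read as a standardized score. The 6 arrays had values for between 7104 and 7154 of 7200 spots. E17 arrays lacked 180 values in all and PH3 arrays 260.

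The deposited scores did not settle which way they run. The slope of the mean score on the curve that the reference pool predicts was -1.23 (95% interval -1.72 to -0.748, over 7145 probes, which are not independent), on the side of sample over reference. It was 0.61 (-0.211 to 1.43) without the 32 probes that differed by more than 2 units, and -0.0458 (-0.436 to 0.345) without PH3 replicate 2. Mean scores also lay far from 0 without a stage difference: their SD was 0.845 over the 4311 probes that differed by less than 0.25 units. It was 1.69 over the 32 that differed by more than 2 units, and the intervals do not allow for this unequal spread. The scores are therefore described as higher or lower at PH3, and whether a higher score stands for more or for less RNA is left open. If the score is reference over sample, a higher score stands for less RNA. Whether the score is a ratio to the pool at all is open as well.

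The probe table gave no usable gene names. It assigned 54 probes to STUB1, a ubiquitin ligase that works with heat shock chaperones. Mean scores of these 54 probes ran from -2.68 to 2.99 with an SD of 1.01, against 0.954 for all tested probes, and 73% of 10000 random sets of 54 probes had a smaller SD. Their within-stage deviations correlated with a median of -0.0127 over 53 probes with 6 values, inside the range of -0.0647 to 0.126 of 1000 random sets. None of the 54 passed the threshold in limma (smallest adjusted p = 0.175), and 9 had an unadjusted p under 0.05, against 6.2 for 54 probes drawn at the rate of all probes. Their stage differences ranged from -1.29 to 0.83. No stage effect on STUB1 or on any other named gene is read from them.

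E17 and PH3 arrays lay apart on the first principal component, which held 38.3% of the variance over 7001 probes with 6 values. E17 arrays had values of -16.95, -23.84 and -8.832 there, and PH3 arrays 12.44, 7.53 and 29.66. The second component (21.7%) set E17 replicate 1 apart at 26.05, while the other 5 arrays lay between -14.8 and 4.528. Correlations across probes between arrays were 0.854 to 0.891 within E17, 0.858 to 0.905 within PH3 and 0.771 to 0.902 between stages, so the ranges overlapped.

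**Figure D1:**
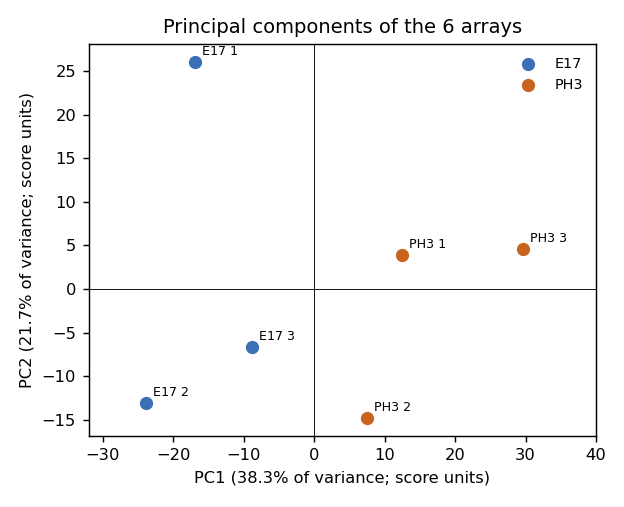
Principal components of the 6 arrays over 7001 probes with 6 values; the axes are PC1 (38.3% of variance) and PC2 (21.7%) in score units, and each point is the array of 1 bird, coloured by stage. All E17 arrays have negative and all PH3 arrays positive values on PC1, and E17 replicate 1 stands apart on PC2.

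The comparison of PH3 with E17 asked which pituitary transcripts differ in abundance across hatching. Of 7145 probes tested with limma, 4 passed an adjusted p of 0.05, and all 4 had a higher score at PH3. Probe 539 had a score of -4.11 ± 0.354 (SD, n = 3) at E17 and -0.268 ± 0.611 (SD, n = 3) at PH3. Its difference was 3.85 (SE 0.326, limma adjusted p = 0.0186). Probe 1621 went from -3.83 ± 0.263 to -0.431 ± 0.609, a difference of 3.4 (SE 0.309, limma adjusted p = 0.0186). The third called probe had a score of -4.38 ± 0.357 at E17 and -1.38 ± 0.503 at PH3, a difference of 3 (SE 0.291, limma adjusted p = 0.0223). The fourth differed in starting level: it was at -0.0417 ± 0.0734 at E17 and at 2.87 ± 0.518 at PH3, a difference of 2.91 (SE 0.256, limma adjusted p = 0.0186). In each of the 4 probes all 3 PH3 arrays lay above all 3 E17 arrays.

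**Figure D2:**
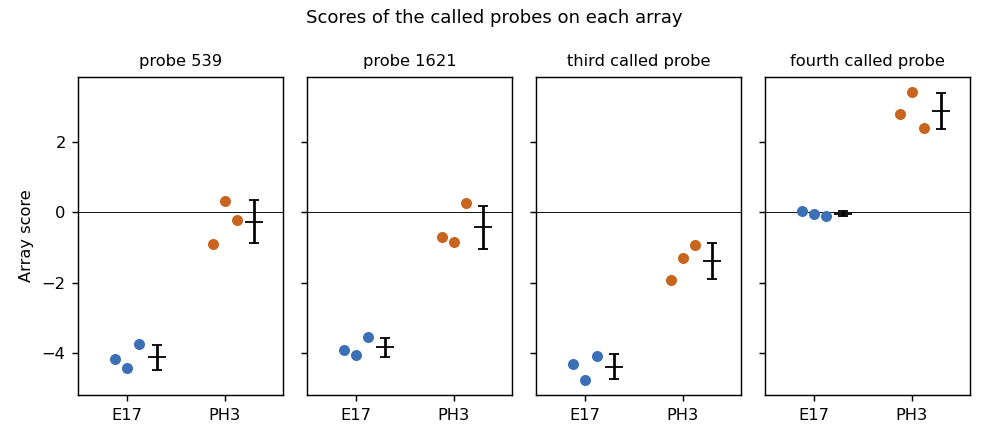
Scores of the 4 called probes; the vertical axis is the array score, each point is 1 bird, and the bar beside the points is the mean ± SD of 3 birds. The first 3 panels have E17 scores between -4.77 and -3.54 and PH3 scores between -1.92 and 0.319, and the fourth has E17 scores between -0.104 and 0.0391 and PH3 scores between 2.4 and 3.42.

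No probe with a lower score at PH3 passed the threshold. The 2 with the smallest unadjusted p were probe 6942, at 1.2 ± 0.0946 (SD, n = 3) at E17 and 0.305 ± 0.167 at PH3, and probe 5510, at -0.335 ± 0.0479 and -1.17 ± 0.154. Their differences were -0.897 (SE 0.15) and -0.839 (SE 0.144), each with a limma adjusted p of 0.15.

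The calls were lost when an E17 bird was left out, while the differences stayed about as large. Without E17 replicate 1 and without E17 replicate 2 limma called 0 probes, with 732 and 557 probes at an unadjusted p under 0.05, and without E17 replicate 3 it called 1, with a lower score at PH3. The 4 probes then differed by 2.799 to 4.035 units, with limma adjusted p between 0.0709 and 0.138. Without PH3 replicate 1, 2 or 3 it called 5, 6 and 3 probes, of which 2, 3 and 2 were among the 4. The 6 without PH3 replicate 2 included 1 with a lower score at PH3. With all 6 arrays, the model without moderation called 0 of 7001 probes with 6 values, with a Benjamini-Hochberg adjusted p of 0.42 for each of the 4, and limma after quantile normalization called 2 of the 4.

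Below the threshold, more probes reached a low p than the test expects by chance, but probes are not independent and such a count can vary widely. An unadjusted limma p under 0.05 was reached by 821 probes (11.5%), against 357.2 expected, with 425 higher and 396 lower at PH3. The balance of directions depended on the setting: it was 457 higher and 346 lower with each array centred on its median, and 264 higher and 397 lower in the model without moderation. Without PH3 replicate 3 the number was 499. Splits of the 6 arrays into 3 and 3 that mixed the stages gave between 61 and 570 such probes. The share of probes with no stage difference was estimated from the p-values as 70.7% by one method (convest) and 81.1% by another (lfdr). Among 7001 probes with 6 values, the 3 scores of one stage all lay on one side of the other in 1307 (18.7%), against the 10% that chance gives, with 536 higher and 771 lower at PH3.

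Large differences were mostly higher scores at PH3. A difference of more than 1 unit was seen in 193 probes, 156 higher and 37 lower, while the median difference over all probes was -0.0334. Single birds moved these counts: 236 were higher without PH3 replicate 2 and 121 without PH3 replicate 3. Without E17 replicate 3 and without PH3 replicate 1, 57 and 60 were lower. Among differences over 1 unit, 80.8% were higher at PH3. Splits of the 6 arrays into 3 and 3 that mixed the stages had between 51.9% and 79.4% in their larger direction, with 77%, 79.3% and 79.4% in the highest of them. A difference of more than 2 units was seen in 26 probes with a higher and 6 with a lower score. Of these 32, 4 of the higher and 5 of the lower had 1 array lying more than 3 units beyond the other 5. The 22 probes over 2 units higher at PH3 whose stages did not overlap had a median score of -3.43 at E17 and -0.88 at PH3, and 20 of the 22 were below -2 at E17, a level that 213 of all 7145 probes reached. Their median within-stage SD was 0.738, against 0.232 for all probes. Choosing the 22 by a large positive difference by itself favours low E17 scores. Their low E17 level is therefore no separate result about these probes.

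**Figure D3:**
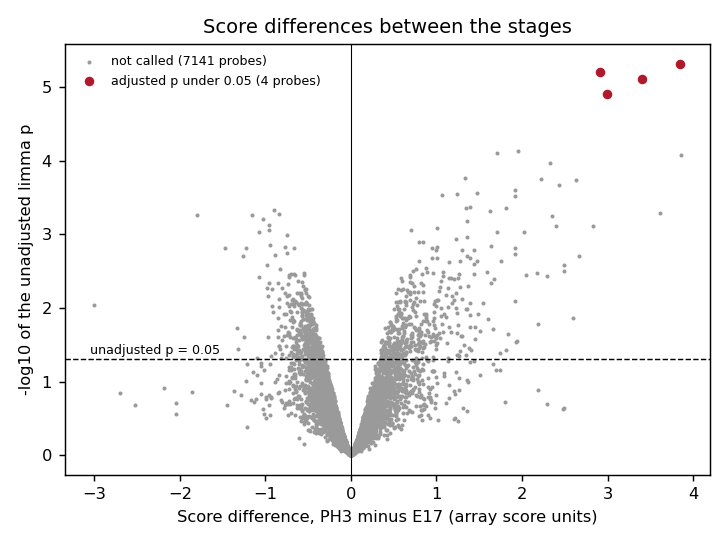
Score difference between the stages (horizontal, PH3 minus E17, in array score units) against -log10 of the unadjusted limma p (vertical) for 7145 probes; the dashed line marks an unadjusted p of 0.05. The 4 called probes lie at differences of 2.91 to 3.85, and differences of more than 1 unit are more frequent on the positive side, with 156 probes against 37.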

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

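The alternatives said here to be added were chosen after the data were seen. The same 4 probes, and no others, were called under median centring, scaling to equal spread, complete probes, robust moderation, array weights and an added standardization of each stretch. Some of these settings changed the scores or probes little, so keeping the calls under them says little. Array medians lay between -0.0768 and -0.0248, stretches already had nearly equal means and spreads, and 7001 of 7145 probes were complete. Quantile normalization kept 2 of the 4. The other added filters dealt with arrays that stand apart on a probe. The first left out 44 probes with 1 array over 3 units from the median of the other 5 and gave 0 calls, since the 4 called probes, whose stages differ by about 3 units or more, were among the 44. It was replaced for that reason, after its result was seen, by leaving out 23 probes with 1 array over 3 units beyond all of the other 5, which gave the same 4 calls. The second form could not remove the 4, whose scores lay close together within each stage (SD at most 0.611). Keeping them there gives no support to the calls. The replicate number as a block gave 32 calls, 31 higher and 1 lower at PH3, with all 4 among them. Deviations of same-numbered samples correlated at 0.0698, 0.119 and -0.0221 over probes. Samples numbered 1 and 2 correlated best with their own number, and those numbered 3 did not. Whether some factor goes with the replicate number therefore stays open. An adjusted p under 0.10 gave 8 calls and one under 0.01 gave 0. The model without moderation gave 0 calls. Leaving out 1 array gave between 0 and 6 calls. Why these settings moved the calls was otherwise not tested. Wherever the 4 probes were tested, their differences stayed positive, between 2.55 and 4.162, with adjusted p between 0.0131 and 0.42. Between 499 and 963 probes had an unadjusted p under 0.05. Probes over 1 unit higher numbered between 121 and 236 and those over 1 unit lower between 24 and 60. The slope that bears on orientation turned to 0.6104 without differences over 2 units (added), was -2.383 with scores multiplied by 0.5 (added), and lay between -1.663 and -0.04583 when 1 array was left out. Gene-level tests, gene lists and the fold threshold were not run, as no gene names were used and scores carry no fold. Limits from signal over background are unknown.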

Other observations

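The tests on matched probe sets, on pairs from different stretches, on probes whose stages did not overlap, on stage medians, and on splits for the numbers of called probes and of probes at an unadjusted p under 0.05 were chosen after the result, or the scores behind it, had been seen. With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. The real split gave 4 calls and the highest other split 0, so that 1 of 10 splits had as many. It gave 821 probes at an unadjusted p under 0.05 and the highest other split 570, again 1 of 10 with as many.

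The 55 probes at least 1.5 units higher at PH3 deviated together among birds of the same stage, with a median correlation of 0.461 (0.349 without PH3 replicate 3), and PH3 replicate 3 was the highest array in 40 of them (72.7%, against 46.3% of 495 non-overlapping probes higher by under 1.5 units) and E17 replicate 2 the lowest in 27 (49.1%, against 45.7%). Neighbouring rows are argued against as the whole source, since pairs from different stretches of 900 rows had a median of 0.4463, against 0.527 within a stretch. How the rows lie on the slide was not known here, so an effect of position on the slide stays open. A stage-related change shared by many probes, further along in some birds than in others, stays open: at an unadjusted p under 0.05 and smaller differences, the median of 0.165 within higher probes passed the bound of 0.1, and those of 0.0591 within lower probes and -0.09301 between directions fell short of 0.1 and -0.1. A scale factor per array acting on extreme scores stays open too: the highest median among 200 probe sets matched on mean score was 0.1709, but these sets were limited to differences under 0.5 and had a median E17 score of -1.19, against -2.23 for the 55, so they decide nothing. Choosing the 55 by their difference may itself favour shared deviations, and they may hold spots of the same transcript; neither was tested.

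Of the differences over 1 unit, 80.83% were higher at PH3, and the highest other split had 79.43% in one direction, so that 1 of 10 splits was as far from 50%, too few for a share under 0.05. Scores that stand apart on 1 array are argued against as the whole source, since 88.11% were higher among probes whose stage medians, which 1 array cannot set alone, differed by over 1 unit; among probes that differed by over 1 unit and whose stages did not overlap, a filter that favours stage differences, it was 88.14%. The lowest share under 3 further normalizations was 75.13%, so more centring and scaling did not remove the excess. The deposited scores already had nearly equal means and spreads in each stretch, so this cannot decide about any centring and scaling done by the authors. A difference between the stages stays open and cannot be told apart from a grouping of single birds, because 6 arrays give too few splits.

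Within-stage deviations of probes in adjacent rows correlated at a mean of 0.123 over the 6 arrays, those 60 rows apart at 0.0885 and those 10 to 50 rows apart at 0.0169. The share of probes at an unadjusted p under 0.05 ran from 7.66% in the eighth stretch of 900 rows to 15.1% in the second.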
